A study of Mus musculus with 4 samples.

How the data were processed

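Total RNA of Epcam-selected small intestinal epithelium at E15.5 was hybridised to Affymetrix Mouse430_2 arrays with a biotin label, 1 array per sample, after precipitation with 10 ug of a carrier, per the labels' protocols. The labels gave 2 controls with floxed Yy1 alleles, described as littermates, and 2 samples that also carried Shh-Cre. Samples of up to 2 pooled embryos were biological replicates per the series design, so p-values measure the spread between such pools. Comparison labels came from the sample titles and genotypes.

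The deposited value table held log2 intensities for 45101 probe sets, made by the authors with GCRMA, which corrects background by probe sequence and normalizes arrays to each other, per the submitters' processing notes. The GCRMA version and settings were not given in the sources used here. Array medians were 2.84 and 2.83 in the controls and 2.88 and 2.89 in the knockouts, and every array had the same lowest value of 2.358. The authors' deposited table of their own comparison held log2 fold changes, p-values and adjusted p-values from limma, and 2 kinds of score, the moderated t and the log odds, per the file headers and the submitters' processing notes. Its log2 changes equalled the knockout mean minus the control mean of the value table to within 0.00748, although its title names the wild type first. Its adjusted p-values corresponded to 22518 probe sets, and all 2156 listed probe sets lay among the probe sets whose interquartile range was above the median. That filter was inferred from the values, and no score was used here.

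The 64 Affymetrix control probe sets were left out of all tests. Gene names came from the platform annotation of the probes: 34945 of the other 45037 probe sets had 1 symbol, 932 had several and 9160 had none listed. Of 34958 probe sets with 1 symbol, 34754 had an Entrez number in the RefSeq gene table (GRCm38.p6), which served only for names. The array files name no genome build, and no coordinates are given. Genes with several symbols per probe set are not named.

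A probe set was tested when its log2 value was at least 4 on at least 2 of the 4 arrays, which left 16887 (37.5%), since GCRMA presses unexpressed probe sets onto a floor. A probe set dim on both arrays of a genotype was tested only if the other genotype was bright, which fixes its direction, and counts of such genes, chosen after the data had been seen, are given beside the lists. The contrast of knockout minus control was fitted with lmFit and eBayes of limma 3.58.1 in R 4.3.3, without covariates, trend or robust options, and adjusted by Benjamini-Hochberg over the tested probe sets. The prior had 3.38 degrees of freedom and an SD of 0.12, and the median SE of a gene's change was 0.12. A gene was represented by its tested probe set with the highest mean among those with 1 symbol, and the threshold was an adjusted p under 0.05, with a log2 change of at least 1 in size for the 2-fold counts. Over probe sets, 2887 were higher and 3381 lower, and 865 and 1058 at least 2-fold. Of 1381 changed genes with further tested probe sets, 985 had another that passed the same way and 126 another of opposite sign, and 17 had probe sets that passed in both directions. Folds are on the scale of GCRMA values, whose floor compresses changes of dim genes.

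The design, the 38 gene lists, the alternatives and the rule for naming genes were fixed before the data were examined. Lists were tested with camera of limma at a preset correlation of 0.01 between genes, with Benjamini-Hochberg adjustment over the 31 lists that had at least 5 tested members, and beside it with an estimated correlation and with fry. With an estimated correlation, the degrees of freedom of camera are limited by the 4 arrays. A list that does not pass that test is therefore not shown to be unchanged. Of the 7 other lists, values and counts are given. List members were matched by symbol or by a listed older symbol, and members without a tested probe set of a single symbol were not analysed here. The rule named Yy1 and Shh, the 8 largest rises and 8 largest falls among genes past the threshold with groups that did not overlap, and up to 4 members of each metabolism list or 3 of any other list by size of change, under the same criteria. Other genes named are said to have been picked out after their values were seen, or stand as values within a list.

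Sex-specific transcripts served as a sample check and had no set test: of 3 tested, none passed, also adjusted over the list alone. Alternatives covered the intensity filter, an offset of 16 before log2, 2 scalings, the variance model, each array left out in turn, the replicate number as a block, the choice of probe sets, the threshold, a test against a 1.2-fold change and the set test. A filter on the interquartile range, a crossed block and counts without lists of other cell types were added after the data had been seen. Where 1 array is left out, the lone array of its genotype is assumed to vary like the other pair.

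The fit was tested on simulated data with 16887 probe sets, 2 against 2 arrays and 200 changed probe sets in each of 10 sets. It recovered 0.149% of changes of log2 0.5, 49.1% of log2 1 and 93.5% of log2 2, with 4.81% false calls, and 4.6% of random lists had a camera p under 0.05. The simulated probe sets varied independently of each other and few were changed, whereas 39.6% of the genes tested passed in the real data. These recovery and false call rates therefore do not carry over to the real data, and the camera rate holds only for genes without correlation. In the real data the arrays' number limits the precision, and a small change that did not pass is not shown to be absent. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.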

Results

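Gene expression was measured on 4 Affymetrix Mouse430_2 arrays. Each was hybridised with RNA of small intestinal epithelium from mouse embryos at E15.5, when villi are forming in the gut. Magnetic selection for Epcam, an adhesion protein on the surface of epithelial cells, had enriched the cells from a stretch of gut that ran from the stomach to the caecum. The 2 control samples carried floxed Yy1 alleles without Cre. The 2 Yy1 knockout samples carried the same alleles with Shh-Cre, a recombinase made from the Shh locus and active in gut endoderm, and each sample held up to 2 embryos of its genotype. Effects of the Cre allele and of the loss of Yy1 can therefore not be told apart in any result given here. Yy1 encodes a zinc finger transcription factor that can activate or repress its targets. The study's title names aerobic metabolism, and the comparison asks which genes, those of mitochondrial energy metabolism among them, differed between epithelium with and without Yy1. Between 35.6% and 36.4% of the probe sets on an array had a log2 value of at least 4. Across the tested probe sets, which are not independent replicates, Pearson's r was 0.990 between the control arrays, 0.989 between the knockout arrays and 0.905 to 0.925 between arrays of different genotype. The number of arrays limits the precision of every value given here. Each log2 change is the knockout mean minus the control mean over 2 and 2 arrays, given with its standard error (SE) from limma.

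Yy1 RNA was lower in the knockout on each of its 4 probe sets. The brightest of them (1422569_at) fell from a log2 value of 8.81 ± 0.02 to 7.04 ± 0.32 (SD, n = 2 each), a log2 change of -1.77 (SE 0.17, limma adjusted p = 0.00209), to 29.3% of the control level. The changes on the other probe sets were -1.85 (1422570_at, adjusted p = 0.00108), -2.09 (1435824_at, adjusted p = 0.00157) and -1.16 (1457834_at, adjusted p = 0.00167), which left 27.7%, 23.4% and 44.7% of the control level. Where these probe sets lie relative to the deleted part of the gene was not established here. Shh, the signalling gene whose locus carries the Cre, fell from 7.40 to 5.45, a change of -1.95 (SE 0.11, adjusted p = 0.000812), to 26.0% of control on 1 probe set, while a further Shh probe set stayed at the lowest values of the arrays (2.37 in both groups). Whether the Cre allele itself or the loss of Yy1 lowered Shh cannot be told apart, since no control carried Cre. Without control 2, the Yy1 change was -1.76 with adjusted p = 0.0504.

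**Figure D1:**
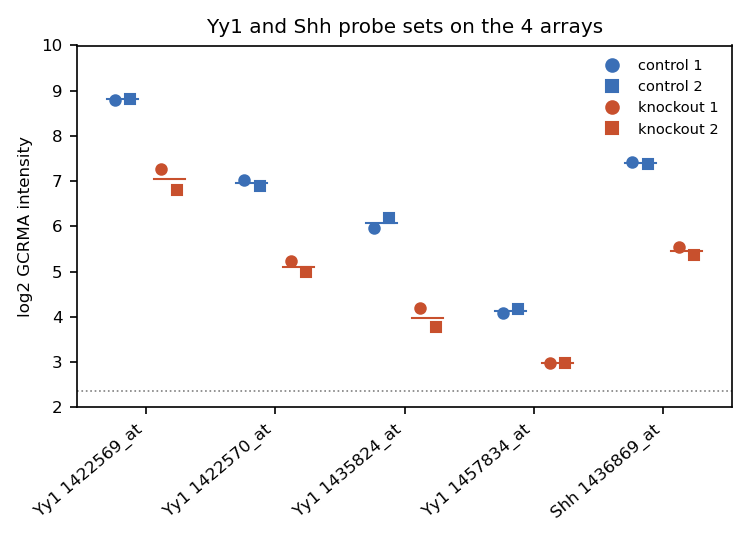
Log2 GCRMA intensity (vertical axis) of the 4 Yy1 probe sets and the brighter Shh probe set on each of the 4 arrays (points), with the mean of each genotype as a short line and the lowest value of the arrays as a dotted line. On every probe set shown, both knockout arrays lie below both control arrays, as for the brightest Yy1 probe set with means of 8.81 and 7.04.

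The 8 largest falls in the knockout included 4 genes of lipid binding and transport, and the 8 largest rises included 5 contractile genes and 2 embryonic globins. The largest falls were those of the alcohol dehydrogenase Adh1 (-6.02 ± 0.29 SE), the mucosal glycoprotein Dmbt1 (-5.62 ± 0.17) and the fatty acid binding protein Fabp1 (-5.44 ± 0.19). They were followed by the apolipoproteins Apoc3 (-5.13 ± 0.40), Apoa1 (-5.13 ± 0.12) and Apoa4 (-5.08 ± 0.44), the microsomal deacetylase Aadac (-4.66 ± 0.26) and the apical endosome protein Mamdc4 (-4.54 ± 0.23). The largest rises were those of the embryonic globins Hba-x (3.97 ± 0.29) and Hbb-y (3.76 ± 0.15), the contractile genes Tpm2 (3.44 ± 0.22), Actg2 (3.43 ± 0.23), Myl9 (3.39 ± 0.31), Acta2 (3.25 ± 0.23) and Myh11 (3.18 ± 0.22), and the matrix protease Adamts9 (3.28 ± 0.35). The adjusted p of these 16 genes lay between 0.000475 and 0.00274. Several means lay close to the lowest value of the arrays, as for Adh1 (2.79) and Aadac (2.49) in the knockout and Hba-x (2.86) in the control, and their folds depend on that floor. Of 8626 genes tested, 1545 were higher and 1871 lower at an adjusted p under 0.05, which is 39.6% of them, and 512 and 620 of these changed at least 2-fold. Both control arrays lay under the intensity filter in 325 of the higher genes and both knockout arrays in 247 of the lower ones. Such genes could be tested only because the other genotype was bright, which fixed their direction. The counts were 537 higher and 896 lower without control 1, 353 and 444 without control 2, 827 and 811 without knockout 1, and 532 and 581 without knockout 2, and Adamts9 (adjusted p = 0.0607) did not pass without control 2. With no filter on low values, only 39 genes were higher and 48 lower.

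All 19 tested enterocyte and villus genes fell, by a median log2 change of -2.58 and a range of -5.44 to -1.10. Among them Fabp1 was 43.4-fold lower (log2 5.91 in the knockout). In 8 of the 19, Apoa4 and Apoc3 among them, both knockout arrays lay under the filter, so that only a fall was possible. All of the other 11 fell too, with a median of -1.80. Adjusted over the list alone, all 19 passed as well. The set test (camera) against all other genes gave an adjusted p of 1.71e-10 (adjusted p = 0.491 with an estimated correlation). Of 15 transcription factors of intestinal identity, 9 fell, 1 rose and 5 did not pass (9 lower and 2 higher adjusted over the list alone), with a median of -0.64. The nuclear receptor Hnf4g fell by 2.78 (SE 0.24, adjusted p = 0.00158), the homeobox factor Cdx1 by 2.74 (SE 0.17, adjusted p = 0.000969) and the homeobox factor Isx by 1.37 (SE 0.17, adjusted p = 0.00366). The member that rose, Foxa2 (1.32, adjusted p = 0.00191), is a forkhead factor of the endoderm and was picked out after its value was seen. For Foxa2, with both controls under the filter, only a rise was possible, and for Cdx1, with both knockouts under it, only a fall. The set test of this list gave adjusted p = 0.0390 (adjusted p = 0.547 with an estimated correlation), and adjusted p = 0.0554 without control 1 and 0.05001 without control 2, and Isx did not pass without control 2 (adjusted p = 0.0643). Markers of other cell types moved beside these genes, the mesenchyme list by a median of 2.21, while 18 general epithelium markers had a median of 0.11.

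**Figure D2:**
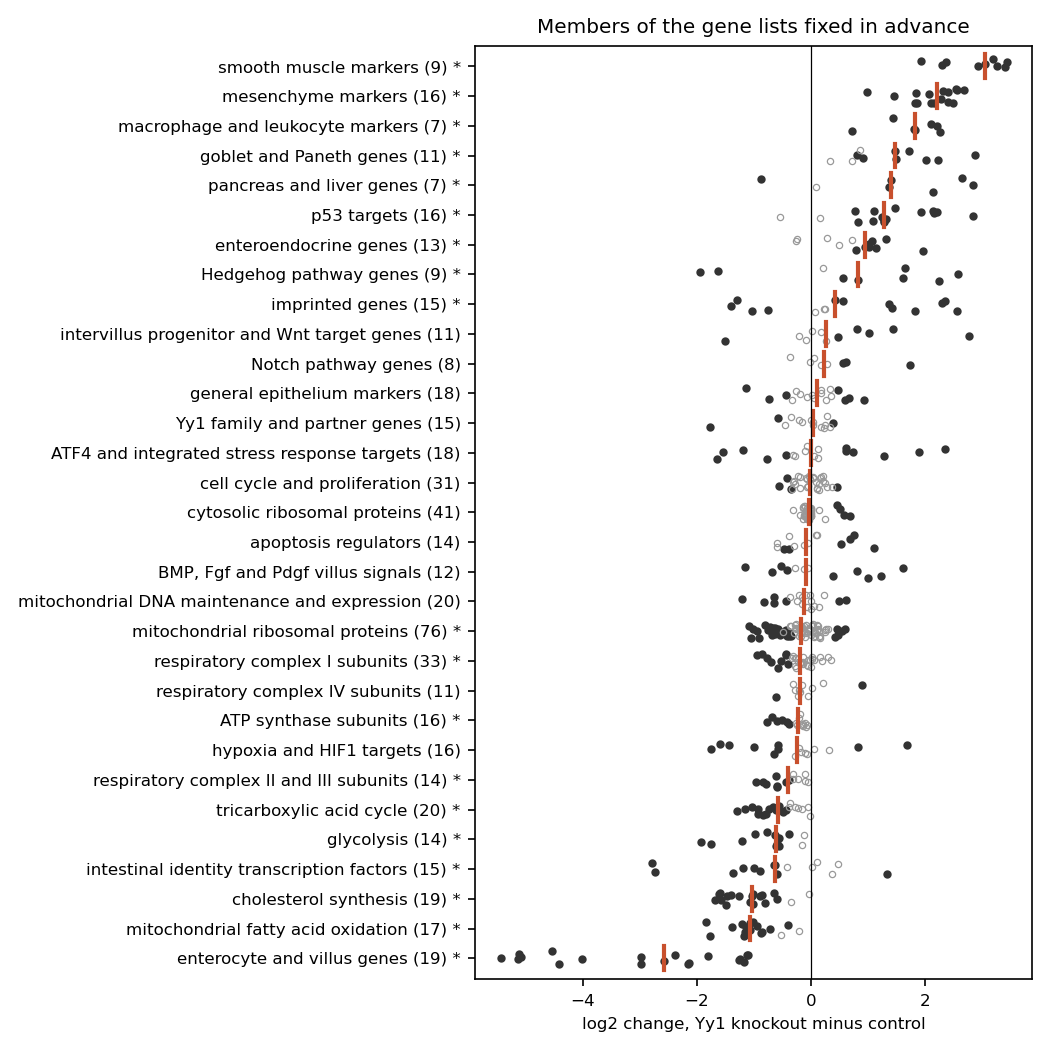
Log2 change from control to Yy1 knockout (horizontal axis) of every tested member of the 31 gene lists with a set test, 1 point per gene, filled where the adjusted p was under 0.05. Vertical bars are list medians, the number of tested genes stands in brackets, and a star marks an adjusted set test p (camera, preset correlation) under 0.05. Enterocyte genes have the lowest median (-2.58) and smooth muscle genes the highest (3.05).

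Most tested genes of fatty acid oxidation and of the tricarboxylic acid cycle were lower in the knockout. On the same arrays the mesenchyme list had a median of 2.21 and the smooth muscle list of 3.05. The 3' minus 5' signal of the Gapdh control probe sets, a measure of RNA quality, was higher in the knockout by 0.29. The same measure differed by 0.04 for the actin probe sets. It compares the ends of 1 transcript and gives no scale for a list median. Whether RNA quality bears on the small medians of complex I (-0.19), complex IV (-0.20) and ATP synthase (-0.23) was not tested. Of 17 fatty acid oxidation genes 15 fell and none rose (16 lower adjusted over the list alone), with a median of -1.06. Among them were the acyl-CoA dehydrogenase Acadm (-1.84 ± 0.17 SE), the isomerase Eci1 (-1.77 ± 0.18) and the carnitine carrier Slc25a20 (-1.38 ± 0.13). Of 20 tricarboxylic acid cycle genes 13 fell and none rose (14 lower adjusted over the list alone), with a median of -0.59. The largest falls were those of the succinyl-CoA ligase subunits Suclg2 (-1.30 ± 0.19) and Sucla2 (-1.17 ± 0.16) and of Dlat (-1.04 ± 0.13) of the pyruvate dehydrogenase complex. Set tests gave adjusted p = 1.21e-06 for fatty acid oxidation and 3.68e-05 for the tricarboxylic acid cycle (adjusted p = 0.503 and 0.510 with an estimated correlation). Of 33 complex I subunits 9 fell and none rose (9 lower adjusted over the list alone, median -0.19), with Ndufc1 at -0.96 ± 0.10 and Ndufs1 at -0.86 ± 0.12. Of 14 genes listed for complexes II and III, which include the carrier cytochrome c (Cycs), 8 fell and none rose (10 lower adjusted over the list alone, median -0.41). Uqcrc1 was at -0.96 ± 0.14 and Sdhc at -0.85 ± 0.12, and 4 of the 14, the Sdh genes, are on the tricarboxylic acid cycle list too. Of 16 ATP synthase genes, which include the inhibitor gene Atpif1, 6 fell and none rose (6 lower adjusted over the list alone, median -0.23), with Atp5b at -0.76 ± 0.10. Their set tests gave adjusted p = 0.0224, 0.00180 and 0.00966 (adjusted p = 0.536, 0.491 and 0.556 with an estimated correlation). Complex IV had 1 of 11 subunits higher, Cox7c (0.90 ± 0.13), and 1 lower, Cox8a (-0.62 ± 0.10), with the same numbers adjusted over the list alone and a set test adjusted p = 0.418. The Cox7c probe set was dim, with a control mean of 5.21 against 9.22 for Cox8a.

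Mitochondrial translation and upkeep genes moved in both directions, by small list medians. The genotypes also differed in the Gapdh 3' minus 5' signal (0.29), less so in that of actin (0.04), and whether RNA quality bears on these medians was not tested. Of 76 mitochondrial ribosomal protein genes 26 fell, 5 rose and 45 did not pass (27 lower and 5 higher adjusted over the list alone, median -0.18), with Mrpl27 (-1.08 ± 0.12 SE), Mrps27 (-1.05 ± 0.13) and Mrps18b (-1.02 ± 0.10) lowest. Their set test gave adjusted p = 0.0171 (adjusted p = 0.491 with an estimated correlation). Of 20 genes of mitochondrial DNA maintenance and expression 5 fell, 2 rose and 13 did not pass, with the same numbers adjusted over the list alone and a set test adjusted p = 0.370. The coactivator Ppargc1b fell by 1.21 (SE 0.14, adjusted p = 0.00303) and the RNA-binding protein gene Lrpprc by 0.83 (SE 0.14, adjusted p = 0.00879). Tfam, a transcription factor that also packages mitochondrial DNA, fell by 0.64 (SE 0.14, adjusted p = 0.0206). Of the 30 genes the rule named from the lists of mitochondrial energy metabolism, translation and upkeep, 15 did not pass without control 1 (adjusted p = 0.0509 to 0.0908), 23 without control 2 (0.0543 to 0.142), 8 without knockout 1 (0.0505 to 0.0791) and 16 without knockout 2 (0.0503 to 0.0972). The set test call of complex I ended with median centring (adjusted p = 0.0523), a further quantile normalization (0.108) and a filter at log2 of 6 (0.0674), and that of the ribosomal proteins with the last 2 (0.0777 and 0.0744) and without control 1 (0.0554).

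Glycolysis genes and cholesterol synthesis genes fell as well, beside the same rise of the mesenchyme list (median 2.21). Of 14 glycolysis genes 12 fell and none rose (12 lower adjusted over the list alone), with a median of -0.61. The lactate transporter Slc16a3 fell by 1.93 (SE 0.12, adjusted p = 0.000924), the phosphofructokinase subunits Pfkp by 1.76 (SE 0.18, adjusted p = 0.00232) and Pfkl by 1.21 (SE 0.10, adjusted p = 0.00152), and the phosphoglycerate kinase Pgk1 by 0.99 (SE 0.10, adjusted p = 0.00234). In 2 of the 14 both knockouts lay under the filter, which left only a fall possible, and 10 of the other 12 fell. Of 19 cholesterol synthesis genes 17 fell and none rose (18 lower adjusted over the list alone), with a median of -1.03. They included the sterol dehydrogenase Nsdhl (-1.68 ± 0.22 SE, adjusted p = 0.00453), the farnesyl diphosphate synthase Fdps (-1.62 ± 0.16, adjusted p = 0.00210) and the sterol sensor partner Insig1 (-1.57 ± 0.20, adjusted p = 0.00414). Set tests gave adjusted p = 7.10e-05 for glycolysis and 4.87e-07 for cholesterol synthesis (adjusted p = 0.491 and 0.503 with an estimated correlation). Hypoxia and HIF1 targets split, with 7 of 16 lower, 2 higher and 7 not passing (7 lower and 3 higher adjusted over the list alone, set test adjusted p = 0.133). Ndrg1 (-1.76 ± 0.18, adjusted p = 0.00250) and the mitophagy receptor Bnip3 (-1.60 ± 0.11, adjusted p = 0.00110) fell, and the carbonic anhydrase Car9 (1.68 ± 0.13, adjusted p = 0.00119) rose. Among the 11 genes the rule named from these 3 lists, 2 did not pass without control 2 (adjusted p = 0.0545 and 0.0576) and 3 without knockout 2 (0.0515 to 0.0661).

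Targets of the tumour suppressor p53 rose together, 14 of 16 higher and none lower (14 higher and 1 lower adjusted over the list alone), with a median of 1.27. Phlda3, an inhibitor of Akt signalling, rose 7.13-fold (log2 2.83, SE 0.11, adjusted p = 0.000686), the polo-like kinase Plk2 rose 4.61-fold (log2 2.20, SE 0.18, adjusted p = 0.00135) and the cyclin Ccng1 rose 4.46-fold (log2 2.16, SE 0.12, adjusted p = 0.000743). The set test gave adjusted p = 2.46e-07 (adjusted p = 0.491 with an estimated correlation), on the same arrays on which the mesenchyme list rose by a median of 2.21. Targets of ATF4 and the integrated stress response went both ways, 6 of 18 higher and 5 lower (the same adjusted over the list alone). The stress genes Nupr1 (2.34 ± 0.21 SE, adjusted p = 0.00174) and Atf3 (1.89 ± 0.10, adjusted p = 0.000737) rose and Cebpb (-1.65 ± 0.10, adjusted p = 0.000899) fell. For Atf3, and for 1 of the p53 targets, both controls lay under the filter, so that only a rise was possible. Their median was -0.01, their mean 0.08 and the direction of the set test up (adjusted p = 0.909). Of 14 apoptosis regulators 4 rose and 2 fell (4 and 3 adjusted over the list alone), and the p53 target Pmaip1 rose most (1.10 ± 0.14, adjusted p = 0.00418). Their median was -0.09, their mean 0.02 and the set test pointed up (adjusted p = 0.909). Of 31 cell cycle genes 1 rose and 3 fell, and none passed adjusted over the list alone (Mki67, picked out after its value was seen, had a log2 change of 0.10, adjusted p = 0.516). Of 41 cytosolic ribosomal protein genes 4 rose and none fell, and none passed adjusted over the list alone. The medians of the last 2 lists, -0.01 and -0.04, turned positive with quantile normalization (0.08 and 0.03), and their set tests gave adjusted p = 0.995 for both. The cell cycle test pointed up against a mean of -0.03, and the ribosomal test pointed down against a mean of 0.003. Of 3 interferon response genes Ifit1 fell at least 5.13-fold, to values at the floor of the arrays (adjusted p = 0.00135), where only a fall was possible, and Bst2 rose by 1.32 (SE 0.15, adjusted p = 0.00308), the same adjusted over the list alone. From these 6 lists the rule named 17 genes, of which 8 did not pass without control 1 (adjusted p = 0.0541 to 0.146), 9 without control 2 (0.0610 to 0.252), 5 without knockout 1 (0.0583 to 0.104) and 8 without knockout 2 (0.0532 to 0.188), the 3 named p53 targets not among them.

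Secretory cell genes were higher in the knockout, on arrays on which the mesenchyme (median 2.21), smooth muscle (3.05), leukocyte (1.83) and pancreas and liver (1.40) lists were higher too. Of 11 goblet and Paneth cell genes 8 rose and none fell (10 higher adjusted over the list alone), with a median of 1.48. The largest rises were those of the intestinal mucin Muc2 (2.87 ± 0.25 SE, adjusted p = 0.00167), the lectin Zg16 (2.23 ± 0.30, adjusted p = 0.00471) and the protease Mmp7 (2.02 ± 0.11, adjusted p = 0.000749). Of 13 enteroendocrine genes 8 rose and none fell (9 higher adjusted over the list alone), with a median of 0.94, and the hormone genes Pyy (1.97 ± 0.11, adjusted p = 0.000738) and Gcg (1.31 ± 0.28, adjusted p = 0.0181) were among them. Set tests gave adjusted p = 2.30e-05 and 0.000660 (adjusted p = 0.503 and 0.491 with an estimated correlation). In 2 genes of each list, Zg16 and Mmp7 among them, both controls lay under the filter, which left only a rise possible. Where both controls lay past it, 5 of 8 goblet and Paneth genes rose (median of the 8, 0.88) and 6 of 8 enteroendocrine genes rose (median of the 8, 1.01). Of 11 intervillus progenitor and Wnt target genes 5 rose and 1 fell (the same adjusted over the list alone, set test adjusted p = 0.0748), with the cell surface receptor Cd44 higher (2.76 ± 0.11, adjusted p = 0.000686) and the stem cell factor Ascl2 lower (-1.52 ± 0.15, adjusted p = 0.00239). The filter fixed both directions, since the Cd44 controls and the Ascl2 knockouts lay under it, and of the other members 4 rose and none fell. Of 8 Notch pathway genes 3 rose and none fell (the same adjusted over the list alone, set test adjusted p = 0.0815), and the ligand Jag1 rose most (1.74 ± 0.16, adjusted p = 0.00189). In 1 of the 8 only a rise was possible. The set test of the Wnt list passed without knockout 1 (adjusted p = 0.0323) and that of the Notch list without knockout 2 (adjusted p = 0.0365), and both lists passed fry (adjusted p = 0.0383 and 0.0432).

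Of 9 Hedgehog pathway genes 6 rose and 2 fell (the same adjusted over the list alone), with a median of 0.83. The ligand Shh was the lowest, but its locus carries the Cre in the knockout samples only, which the loss of Yy1 cannot be told apart from. The member with the largest rise was Gas1 (2.57 ± 0.22 SE, adjusted p = 0.00156), a co-receptor, followed by Foxf1 (2.24 ± 0.16, adjusted p = 0.00109), a transcription factor of gut mesenchyme. The ligand gene Ihh, picked out after its value was seen, fell by 1.64 (adjusted p = 0.00190). The set test gave adjusted p = 0.0224 (adjusted p = 0.491 with an estimated correlation), and the mesenchyme list, of which Foxf1 and Gas1 are not members, moved beside it by a median of 2.21. Both controls lay under the filter in 4 of the 9, Gas1 and Foxf1 among them, so that only a rise was possible, and of the other 5 only 2 rose, with a median of 0.21. Of 12 BMP, Fgf and Pdgf villus signals 5 rose and 4 fell (the same adjusted over the list alone), with the BMP ligands Bmp4 higher (1.60 ± 0.10, adjusted p = 0.000928) and Bmp2 lower (-1.16 ± 0.14, adjusted p = 0.00383). Their median was -0.09, their mean 0.15 and the direction of the set test up (adjusted p = 0.857, fry adjusted p = 0.0219), and in 3 of them, Bmp4 among them, only a rise was possible, and in 2, Bmp2 among them, only a fall. Among the 18 genes named from the 6 lists of secretory cells, progenitors and signals, 5 did not pass without control 1 (adjusted p = 0.0572 to 0.110), 6 without control 2 (0.0505 to 0.189), 4 without knockout 1 (0.0535 to 0.133) and 5 without knockout 2 (0.0519 to 0.124).

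**Figure D3:**
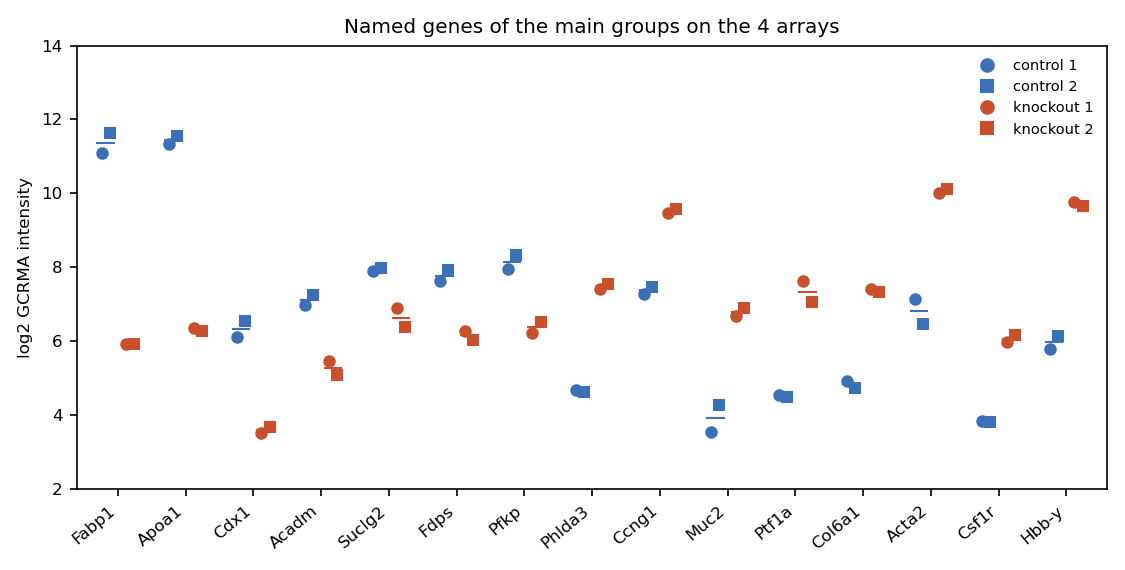
Log2 GCRMA intensity (vertical axis) of 15 genes on each of the 4 arrays (points), with the mean of each genotype as a short line. From left to right stand genes of enterocytes and intestinal identity, of metabolism, of the p53 response, and of secretory, pancreatic, mesenchymal, muscle, macrophage and blood cells, and Fabp1 falls from a mean of 11.35 to 5.91 where Acta2 rises from 6.81 to 10.06.

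Pancreatic genes were higher in the knockout, beside the rise of the mesenchyme list (median 2.21). Of 7 tested pancreas and liver genes 5 rose and 1 fell (the same adjusted over the list alone), with a median of 1.40. The pancreatic transcription factor Ptf1a rose 7.10-fold (log2 2.83, SE 0.20, adjusted p = 0.00109), the lipase Cel 6.24-fold (log2 2.64, SE 0.30, adjusted p = 0.00320) and the carboxypeptidase Cpa1 4.39-fold (log2 2.13, SE 0.15, adjusted p = 0.00109), and Afp, picked out after its value was seen, fell by 0.89. In 1 of the 7 both controls lay under the filter, and of the other 6 members 4 rose. The control arrays already held Cpa1 RNA at a mean log2 of 8.66. The set test gave adjusted p = 0.0142 (adjusted p = 0.565 with an estimated correlation). With no intensity filter the list had 11 members, a median of 0.08 and adjusted p = 0.199. Only 2 genes of the stomach and oesophagus list were tested, the gastric secreted protein Gkn1 (2.70 ± 0.19 SE, adjusted p = 0.00107) and the tight junction gene Cldn18 (2.39 ± 0.11, adjusted p = 0.000686). Both passed, also adjusted over the list alone, but their controls lay under the filter, so that a rise was the only direction open to them. Cel did not pass without control 1 (adjusted p = 0.0508) or without control 2 (adjusted p = 0.0644).

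Markers of other cell types were mostly higher in the knockout preparations, although the cells had been selected for Epcam. All 16 tested mesenchyme markers rose, with a median of 2.21, among them the matrix gene Dcn (2.68 ± 0.24 SE, adjusted p = 0.00169) and the collagen gene Col6a1 (2.54 ± 0.12, adjusted p = 0.000686). All 9 smooth muscle markers rose, with a median of 3.05 and values up to 3.43 for Actg2, and all 7 macrophage and leukocyte markers rose, with a median of 1.83 and values up to 2.25 for the receptor Csf1r (SE 0.11, adjusted p = 0.000726). Both controls lay under the filter, which left only a rise possible, in 7 of the mesenchyme, 3 of the smooth muscle and 3 of the leukocyte markers, Dcn and Csf1r among them. Where both controls lay past it, 8 of 8, 5 of 5 and 2 of 2 rose, with medians of 2.35, 3.25 and 1.96. Each of the 32 genes also passed adjusted over its list alone, and set tests gave adjusted p = 6.94e-11, 2.46e-07 and 2.30e-05 (adjusted p = 0.491 with an estimated correlation for each). Of 3 erythroid markers the globins Hba-x, with controls under the filter, and Hbb-y rose and Tfrc, the transferrin receptor that many cells carry, fell by 0.96 (SE 0.11, adjusted p = 0.00321). The endothelin receptor Ednrb, the only neuron and glia marker tested, with controls under the filter, rose by 1.96 (SE 0.22, adjusted p = 0.00290), and the only endothelium marker tested, Egfl7, fell by 0.57 (SE 0.15, adjusted p = 0.0381). Of 3 mesothelium markers Upk3b fell by 2.39 (SE 0.15, adjusted p = 0.000919) and Cav1, with controls under the filter, rose by 1.46 (SE 0.10, adjusted p = 0.00107). Calls in these 4 small lists were the same adjusted over the list alone, except that the mesothelium list then had 2 genes lower. General epithelium markers went both ways, 4 of 18 higher and 3 lower (5 and 4 adjusted over the list alone, set test adjusted p = 0.606), with the tight junction genes Cldn4 at 0.92 ± 0.14 and Ocln at -1.13 ± 0.14. Epcam itself, picked out after its value was seen, fell from 11.52 to 11.08 (-0.44, SE 0.11, adjusted p = 0.0287). Of the 19 genes named from these 8 lists, 2 did not pass without control 1 (adjusted p = 0.0694 and 0.158), 5 without control 2 (0.0583 to 0.0841), 1 without knockout 1 (0.106) and 2 without knockout 2 (0.0532 and 0.198).

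Of 15 imprinted genes 8 rose and 4 fell (the same adjusted over the list alone), with a median of 0.42 and set test adjusted p = 0.0390 (adjusted p = 0.491 with an estimated correlation). Those with the largest rise were Dlk1 (2.56 ± 0.16 SE, adjusted p = 0.000964), Mest (2.34 ± 0.17, adjusted p = 0.00113) and Ndn (2.30 ± 0.24, adjusted p = 0.00244). In 1 of the 15 only a rise and in 1 only a fall was possible under the filter. Dlk1 is also on the mesenchyme list, whose median was 2.21. The set test call ended with quantile normalization (adjusted p = 0.0777), median centring (0.0587), without control 2 (0.0914), without knockout 1 (0.0800) and without probe sets that can match several transcripts (0.0647). Of 15 genes of the Yy1 family and its chromatin partners, Yy1 and the Polycomb gene Suz12 (-0.58 ± 0.14, adjusted p = 0.0263) fell and the remodeller gene Ino80 (0.38 ± 0.10, adjusted p = 0.0380) rose, and only Yy1 passed adjusted over the list alone. The list's median was 0.03 and its mean -0.12, and the set test pointed up (adjusted p = 0.922). Among the 6 genes named from these 2 lists, 2 did not pass without control 1 (adjusted p = 0.0618 and 0.115), 3 without control 2 (0.0504 to 0.157), 2 without knockout 1 (0.0840 and 0.114) and 2 without knockout 2 (0.101 and 0.150).

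Across the 31 lists with at least 5 tested members, the set test called 19, of which 9 were higher and 10 lower, and 18 of the 19 also passed fry, which asks whether a list's genes move one way and compares them with no other genes. In all fry called 21 lists, with those of intervillus and Wnt targets, Notch, and BMP, Fgf and Pdgf signals added. The exception was the pancreas and liver list (fry adjusted p = 0.0575). None of the 31 passed with an estimated correlation between genes. The authors' deposited table listed 2156 probe sets, 1010 higher and 1146 lower in the knockout, each with a log2 change of at least 1 in size. The intensity filter left 1935 of these to be tested here, and 1923 of them were past the threshold, all with the sign of the authors' deposited table. That table was made with limma from the same arrays, so the shared sign was fixed in advance and is no independent support.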

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

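Tests of the added genes of other cell types, of the p53 targets against the other cell types and of the acinar and gastric genes were set before their results were seen. The other tests of this part, on an even rise of other cell types, on dilution and on the Cre allele, were chosen after the result was seen.

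The control probe sets for Gapdh, which no comparison used, differed between genotypes. The log2 signal of the 3' end minus that of the 5' end was 1.31 and 1.37 on the control arrays and 1.60 and 1.65 on the knockout arrays, a difference of means of 0.29, while the actin probe sets differed by 0.04.

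Genes of mesenchyme (median 2.21), smooth muscle (3.05) and leukocytes (1.83) and 2 embryonic globins were higher in the knockout, and their most abundant members were Acta2 (log2 10.06 in the knockout, 6.81 in the control), Hbb-y (9.71, 5.96), Col1a1 (9.33, 7.17) and Laptm5 (8.07, 6.24). A lower epithelial share that raised all types alike was set to give similar medians for smooth muscle and mesenchyme. Among members with both controls past the filter, the smooth muscle median exceeded the mesenchyme median by 0.90, more than the larger SD of 0.63. This cannot decide, because a gene's log2 change also depends on the RNA that the controls already held and on the floor. Of single markers of further types, Upk3b fell by 2.39 and Egfl7 by 0.57. Cav1, on the same mesothelium list as Upk3b, rose by 1.46, with controls under the filter. For the fall of enterocyte, fatty acid oxidation and tricarboxylic acid cycle genes, dilution by cells that lack general epithelium markers was tested on these markers. As a list they did not fall, with a median of 0.11 and a bootstrap 95% interval of -0.20 to 0.33, above the median of -0.59 for the tricarboxylic acid cycle. They did not move as 1, with 4 of 18 higher and 3 lower, Epcam among the lower. The interval treats the genes of a list as independent and does not measure the spread between samples. Such dilution is therefore not excluded. Dilution by other cells that bear Epcam, such as acinar cells, cannot be judged from these markers and stays open. More mesenchyme, muscle, blood and leukocyte cells in the knockout preparations was tested on 13 further genes with both controls past the filter. Of these, 5 were higher (38.5%, against 17.9% of all tested genes, those with dimmer controls included). That is a smaller share than had been predicted, and low enough to count against such a gain under the rule set beforehand. All 5 were among 9 mesenchyme and muscle genes, such as Fstl1 (1.94) and Flna (2.16). None of 3 leukocyte genes and 1 erythroid gene was higher, and Lcp1 fell by 1.23 (adjusted p = 0.00502). The test cannot decide, because RNA that the controls already hold can hide a gain of other cells. The median control mean was 6.69 in those not higher and 5.25 in those higher. With dimmer controls included, 10 of 14 mesenchyme and muscle genes rose and 0 fell, and of 4 leukocyte genes 1 rose and 1 fell. In 5 of the 14 and 1 of the 4 only a rise was possible. A gain of these cell types past the Epcam selection, or of mesenchyme and muscle cells alone, stays open. Expression of these genes by the epithelium was not tested apart from it and stays open too.

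The rise of p53 targets (median 1.27) has 2 explanations that stayed open beside the loss of Yy1. RNA brought by other cell types could add to it: between the control arrays, where the mesenchyme median differed by 0.29, the median p53 target differed by -0.0717 (control 1 minus control 2), but a single pair of arrays decides nothing. The Shh-Cre allele and the loss of Yy1 cannot be told apart, because 0 control arrays carried Cre. The same holds for every other difference between the genotypes. Of the 16 targets, 14 had a control mean of at least 4.

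Pancreatic acinar genes offered a test on members not looked at before: 9 of 11 were higher (81.8%, against 17.9% of all tested genes), and of the 9 whose controls both lay past the filter, 7 were higher, while Cpb1 (1.95, adjusted p = 0.0560) and Spink1 (0.27, adjusted p = 0.344) did not pass. Acinar cells or pancreatic tissue in the preparations is a candidate explanation, since acinar cells bear Epcam and the selection would keep them, and 5 of 18 acinar genes had a control mean of at least 8, such as Ctrb1 at 11.12. The knockout arrays stood apart on some of these genes, as for Prss2 (6.89 and 5.58), Reg1 (6.86 and 5.54) and Cpb1 (7.45 and 5.56), by a median of 0.57 on the pancreas and liver list and 0.19 on the 11 genes, and the rises were unequal, from 0.63 for Rab3d to 2.83 for Ptf1a. Of gastric genes not looked at before, 100% were higher, but these were only Muc1 (1.69, with controls under the filter) and Ctse (0.47), too few to decide. A change of regional identity in the epithelium stays open as untested.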

How the results depend on the processing

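The filter on interquartile range, the crossed block and the counts without lists of other cell types were chosen after seeing the data. With no intensity filter, 39 genes were higher and 48 lower (26 and 22 at least 2-fold), 68 of the probe sets in the authors' deposited table passed, and the Yy1 change of -1.77 had adjusted p = 0.123 (0.0504 at most over the arrays left out); 15516 of 45037 probe sets then had a residual SD under 0.01, and the prior degrees of freedom fell from 3.38 to 0.363. A filter at log2 of 6 tested 4864 genes and gave 915 higher, 196 of them at least 2-fold, and 362 lower at least 2-fold. The offset of 16, which damps changes of dim genes, gave 241 higher and 348 lower at least 2-fold. An adjusted p under 0.01 gave 718 higher and 893 lower. With 1 array left out, which leaves fewer samples, the ranges were 353 to 827 higher and 444 to 896 lower, 322 to 502 and 386 to 646 at least 2-fold, a Yy1 change of -1.996 to -1.54 and 17 to 20 lists called. With an estimated correlation, 0 lists were called. The replicate number as a block gave 1280 genes higher and 1587 lower; same-numbered arrays deviated from their group means with a correlation of -0.31 (-0.18 without sex-specific transcripts), so the numbers are not shown to pair the samples. The crossed block gave 1591 higher and 1924 lower. Without the lists of other cell types, 1509 were higher and 1868 lower. Counts under the other settings stayed within 1.5 times. No named gene changed sign under any setting in which it was tested, and of 119 named genes 112 did not pass with no filter, 33 without control 1, 51 without control 2, 20 without knockout 1, 36 without knockout 2 and 5 with the block. Signal over background limits the tests: 37.5% of probe sets were bright enough to be tested.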

Other observations

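The endocytosis and lysosome test was set before its result was seen, on a list written after the falls of Cubn and Mamdc4 had been noticed.

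The fetal enterocyte takes up proteins through an apical endocytic apparatus with large lysosomes. The receptor gene Cubn fell by 2.98 (SE 0.23, limma adjusted p = 0.00122) and Mamdc4 by 4.54 (SE 0.23, adjusted p = 0.000737). The hypothesis was that the fall extends to other genes of this apparatus. Of 16 further tested members 9 fell (56.2%, against 21.7% of all tested genes), and their median was -0.63. Both knockouts lay under the filter for 1 of them, Amn, and of the other 15 members 8 fell. Amn, the membrane partner of Cubn, fell by 2.17 (SE 0.12, adjusted p = 0.000738), the sialidase Neu1 by 1.77 (SE 0.25, adjusted p = 0.00541), the carboxypeptidase Scpep1 by 1.60 (SE 0.17, adjusted p = 0.00259) and the lysosome membrane gene Lamp1 by 0.77 (SE 0.10, adjusted p = 0.00453). The cathepsin gene Ctsd had a log2 change of 0.01 (adjusted p = 0.945), and Clu, a secreted chaperone, rose by 2.34 (SE 0.14, adjusted p = 0.000812). Among genes of endocytosis, Dab2 (-0.24, adjusted p = 0.284), Cltb (-0.09, adjusted p = 0.534) and Ap2a1 (-0.15, adjusted p = 0.344) did not pass, while Amn and Dab1 (-1.59, adjusted p = 0.00246) fell. The share that fell meets the hypothesis as it was set, but not every part of the apparatus fell. Enterocyte genes, which fell by a median of 2.58, moved on the same arrays.

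Transcripts of the X inactivation gene and of the Y chromosome split the arrays within each genotype. Xist (1436936_s_at) had log2 values of 10.27 on control 1 and 9.89 on knockout 2, against 3.49 on control 2 and 2.67 on knockout 1. Eif2s3y was at 6.53 on control 2 and 6.75 on knockout 1, against 2.41 on the other two arrays, and Kdm5d was at 6.18 and 6.02 against 2.38 and 2.38. The group differences of Xist (-0.59), Eif2s3y (0.11) and Kdm5d (-0.08) did not pass.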
